A study of Mus musculus with 6 samples.

How the data were processed

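The libraries were made from liver RNA of C57BL/6 mice that received cadmium chloride by gavage at 20 mg per kg per day for 90 days, and of control mice given 0 mg per kg. Per the labels' protocols the mice were male, 6 were assigned to each group, and fragmented RNA was split by an antibody against N6-methyladenosine (m6A, a methyl mark on RNA). The 6 libraries used here are the input fraction, 3 per group, and the labels describe that fraction as the RNA the antibody did not bind. Antibody-bound libraries were not analysed here. Libraries were built with a low-input total RNA kit and read as 150-base pairs on a NovaSeq instrument, per the labels' protocols. The labels do not say how the 6 mice of a group map to its 3 libraries, so p-values measure the spread between these libraries.

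The first deposited table holds FPKM (fragments per kilobase of gene, scaled to the total of each library) for 55335 genes, given by identifier only. The authors' second deposited table holds log2 values for 34352 genes with symbols, the mean of each group, and the authors' own log2 fold change, p-value and FDR per gene. Per the submitters' processing notes cutadapt 1.1.8, STAR 2.7.1a, SAMtools 1.3.1, MACS2 2.1.1 and DESeq2 were used with the mm10 genome, with no role or order given. The read counter, the annotation release and the test behind the deposited p-values are not given in the sources used here. No columns of the 2 tables were left unused as samples of unknown origin.

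The unit of the second deposited table was worked out from its values: the numbers obtained by undoing log2 and subtracting 1 were whole multiples of 1 step per library. That is the pattern of read counts divided by a size factor, and 100% of the values above 0 came out whole within 0.05 of a read. The recovered totals were 59095817, 50117621 and 42476574 reads in control replicates 1 to 3, and 42115960, 68587128 and 65662619 in cadmium replicates 1 to 3. FPKM per recovered read stayed within 10 percent of its library-adjusted mean for 100% of 9317 genes with FPKM of at least 1 in 3 libraries and 50 reads in each.

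The comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend and robust moderation, two-sided, over the 9908 genes with FPKM of at least 1 in at least 3 of the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. The design fixed beforehand called for a count model only if a table held raw counts. The second table holds log2 values, so the FPKM fit stayed the main one, and limma's voom method on the recovered reads was added after the data were seen. No count-based package was run.

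FPKM are scaled to each library's total, and the most abundant RNA species take much of that total: the 10 genes with the most reads held 44.4% of reads in control replicate 1 and 33.2% to 35.7% in the others. The median log2 fold change of all 9908 genes was 0.09 in FPKM, -0.01 after quantile normalization and -0.06 in the deposited log2 values. Medians of gene lists are therefore given relative to the median of all genes.

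Each library carries a number from 1 to 3 that the labels also give as its batch, and each batch holds 1 control and 1 cadmium library. The pairing therefore comes from the labels. Deviations from the group means correlated across genes at -0.21, -0.23 and -0.02 between same-numbered libraries, and at -0.10 to 0.28 in the 6 pairs of a control and a cadmium library with different numbers. The highest of these joined control replicate 1 and cadmium replicate 2. Mitochondrial rRNA held 0.265% and 0.277% of reads in these 2 libraries and 0.782% to 1.18% in the others, and Alb held 2.87% and 2.91% against 4.89% to 5.06%. Why these 2 libraries resemble each other was not tested. The fit with the number as a block is given beside a result wherever it ended a call or moved a count by more than 1.5 times.

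A set of 40 gene lists (pathways, liver cell types, tissue contamination and RNA quality) was fixed before the data were examined. Lists with at least 4 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and p-values were adjusted over the 33 lists tested. The genes named were also set by a rule fixed before the data were examined. It takes the 10 largest called changes in each direction with non-overlapping groups, passing over predicted genes named Gm with digits or ending in Rik. It adds up to 4 members of each list with the smallest p, 15 genes of metal handling, oxidative stress, m6A and liver function, and the 5 genes of highest FPKM in each group. 1 gene of the fixed lists is not reported here and was left out of the tests on single genes that were chosen after the data were seen. Genes outside that rule are said to have been chosen after their values were seen.

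Coordinates are those of GENCODE M21 on GRCm38, the assembly called mm10, matched by identifier for 55154 of 55335 genes, counted from 1. The script was tested on simulated data of the same size with 200 changed genes among 9695 tested. It recovered 64 of 100 genes changed 2-fold and 90 of 100 changed 4-fold, with 5 false calls. With no gene changed it called 0. The simulated genes were drawn independently and carried no shift in scaling between the groups. In the data, FPKM relative to the normalized counts had a median log2 ratio of -0.16 to -0.05 in the control libraries and 0.07 to 0.13 in the cadmium libraries. The simulation therefore does not cover false calls from such a shift. Alternatives covered the pseudocount, the filter, scaling, the variance model, library weights, the block, each left-out library and a fold minimum. The planned swap of 1 count package for another was not run, since no table is given as counts.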

Results

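Liver RNA was profiled in 3 libraries from control mice and in 3 libraries from mice given cadmium chloride by gavage for 90 days, a metal salt whose ion is taken up by hepatocytes and bound there by metallothioneins. Recovered totals ran from 42115960 to 68587128 reads per library. The highest mean FPKM in both groups belonged to the 7SL RNA genes Rn7s1 and Rn7s2, at 249699 ± 60819 and 248177 ± 63424 (SD, n = 3) in controls and 226281 ± 33467 and 222733 ± 32992 in cadmium. They were followed by Gm12896, Gm12895 and Gm23935, predicted genes, and the near-identical members of each pair can share reads. Protein-coding genes held 55.5% of reads in control replicate 1 and 64.0% to 68.1% in the others. The principal component with the most variance, 42.1%, parted the groups, and the next, 26.2%, placed control replicates 1 and 2 at opposite ends. Correlations across genes were 0.962 to 0.979 within controls, 0.977 to 0.983 within cadmium and 0.951 to 0.968 between groups. Genes are not independent replicates, so these values describe resemblance only. All 6 libraries carried Xist, the RNA of the inactive X chromosome, at 19.7 to 35.5 FPKM, although the labels give male mice.

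The comparison of cadmium with control asks which liver transcripts differ in the input fraction after 90 days of exposure. Per the labels that fraction is RNA the m6A antibody did not bind. A change in abundance cannot be told apart here from a change in the share bound. Statements that a gene rose or fell refer to its level in that fraction. Mt1, Mt2, 14 of 22 interferon-stimulated genes and 14 of 16 matrix genes were called higher in cadmium. Called lower were 9 of 17 clock genes, of which 3 others were called higher, 5 of 17 heat shock proteins and the heme enzyme Alas1. Of 9908 genes tested, 779 were called higher and 180 lower in cadmium at an adjusted p of 0.05 (limma), and 2674 passed an unadjusted p of 0.05. All 959 called genes had groups that did not overlap. Over all tested genes 33.6% did not overlap, where chance gives 10%. The split between directions varied with the scaling: quantile normalization gave 347 higher and 298 lower, trimmed mean scaling 365 and 286, upper quartile scaling 510 and 233, and the deposited log2 values 381 and 493. With the replicate block 184 were higher and 64 lower. Without cadmium replicate 3 the total was 101, without cadmium replicates 1 or 2 it was 317 or 561, and without control replicates 2 or 3 it was 524 or 372.

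Mt2 and Mt1, the metallothioneins that bind cadmium and zinc, showed 2 of the 3 largest upward changes. Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) rose from 10.6 ± 7.67 to 951 ± 312 FPKM (SD, n = 3), a ratio of means of 90.0 and a log2 fold change of 6.52 (SE 0.52, adjusted p = 0.00688). Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327) rose from 23.3 ± 17.0 to 564 ± 176 FPKM, a log2 fold change of 4.77 (SE 0.62, adjusted p = 0.0149), and its adjusted p was 0.0838 without cadmium replicate 3. Of the 20 measured metal-handling genes 6 rose and 1 fell, against 8 and 1 adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.231). The counts with the replicate block were 2 and 1. Tfrc, the transferrin receptor that imports iron, was the gene that fell, from 5.95 ± 1.75 to 0.948 ± 0.118 FPKM (log2 fold change -1.81, SE 0.17, adjusted p = 0.00508; chromosome 16, 32608920 to 32632794). Slc39a8, an importer of zinc, manganese and cadmium, rose from 1.84 ± 0.11 to 2.96 ± 0.17 FPKM (adjusted p = 0.0143, and 0.0613 with the block). The zinc exporter Slc30a1 rose from 8.64 ± 0.86 to 16.4 ± 4.49 FPKM (adjusted p = 0.0342, and 0.0527 with the block). Slc39a14, a related importer, was at 15.9 ± 1.23 and 14.9 ± 1.10 FPKM (adjusted p = 0.659). The call for Slc39a8 was lost without cadmium replicate 3 (adjusted p = 0.0663). The call for Slc30a1 was lost without every library but cadmium replicate 1, with adjusted p up to 0.0902, and after quantile normalization (adjusted p = 0.0526), after trimmed mean scaling (0.0556) and in the deposited log2 values (0.0505).

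**Figure D1:**
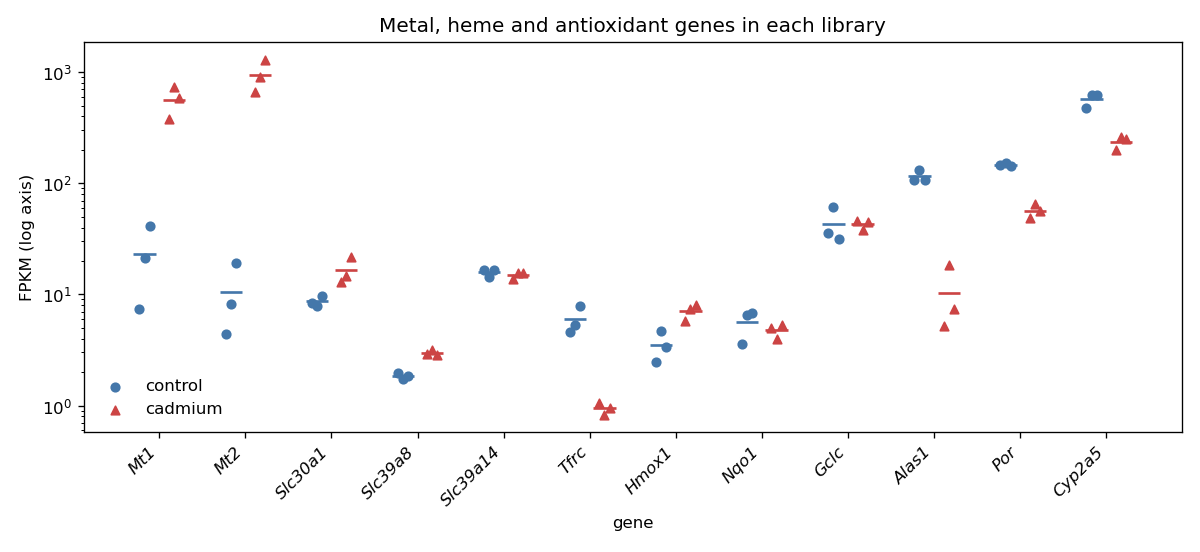
FPKM of 12 metal, heme and antioxidant genes in each library, on a log axis, with control libraries as circles, cadmium libraries as triangles and group means as bars. Mt2 stands at a mean of 10.6 FPKM in control and 951 in cadmium, and Tfrc and Alas1 lie lower in all 3 cadmium libraries than in any control library.

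Alas1, the rate-limiting enzyme of heme synthesis in liver, fell from 115 ± 13.5 to 10.3 ± 6.98 FPKM (log2 fold change -3.54, SE 0.41, adjusted p = 0.0114; chromosome 9, 106233455 to 106248654). Its adjusted p was 0.0547 without cadmium replicate 3. Hmox1, which degrades heme, rose from 3.52 ± 1.13 to 7.05 ± 1.15 FPKM (log2 fold change 0.85, SE 0.20, adjusted p = 0.0402), a call lost without any library but control replicate 2, with adjusted p up to 0.140, and missed in the deposited log2 values (0.0502). Among 25 measured NRF2 antioxidant genes 1 rose and 1 fell, the same numbers as adjusted over the list alone, and the list was not called (adjusted p = 0.228). With the block 1 rose and 0 fell. Hmox1 was the gene that rose. Gstp1, a glutathione transferase, fell from 114 ± 14.4 to 69.6 ± 9.11 FPKM (adjusted p = 0.0368, and 0.102 with the block), a call that was kept in 1 of the 6 fits that left out a library, that without control replicate 1. Nqo1 was at 5.66 ± 1.81 and 4.79 ± 0.70 FPKM (adjusted p = 0.679) and Gclc at 42.9 ± 16.5 and 42.7 ± 4.27 FPKM (adjusted p = 0.920).

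Drug-metabolising enzymes were called lower as a list. Of 55 measured members 2 rose and 6 fell, against 2 and 7 adjusted over the list alone, and the median log2 fold change lay -0.23 from that of all genes (camera adjusted p = 4.17e-06). The adjusted p was 0.574 with an estimated correlation, and with the block 0 rose and 3 fell. Por, which passes electrons to microsomal cytochromes, fell from 147 ± 5.81 to 56.9 ± 8.43 FPKM (log2 fold change -1.37, SE 0.15, adjusted p = 0.00739). Cyp2a5, the mouse coumarin hydroxylase, fell from 576 ± 85.7 to 238 ± 33.6 FPKM (adjusted p = 0.0133). Fmo2, a monooxygenase, fell from 7.83 ± 1.30 to 3.73 ± 0.53 FPKM (adjusted p = 0.0133), and Ces1d, a carboxylesterase, from 229 ± 11.5 to 125 ± 5.64 FPKM (adjusted p = 0.0133, and 0.0516 with the block). Without cadmium replicate 3 the calls of Cyp2a5, Fmo2 and Ces1d were lost, at adjusted p of 0.0606, 0.0652 and 0.0792.

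Heat shock proteins were called lower as a list. Of 17 measured 0 rose and 5 fell, against 0 and 7 adjusted over the list alone, with a median -0.54 from that of all genes (camera adjusted p = 1.34e-10). That adjusted p was 0.398 with an estimated correlation, and 3 fell with the block. The chaperone Hspa8 fell from 120 ± 24.0 to 60.9 ± 12.1 FPKM (adjusted p = 0.0339) and its partner Dnaja1 from 13.6 ± 2.81 to 6.52 ± 0.90 FPKM (adjusted p = 0.0177). Dnajb1 fell from 4.94 ± 0.28 to 3.13 ± 0.46 FPKM and Chordc1 from 2.98 ± 0.15 to 1.59 ± 0.27 FPKM, with adjusted p of 0.0244 and 0.0133, or 0.0627 and 0.0503 with the block. Leaving out cadmium replicate 3 ended all 4 calls and gave adjusted p up to 0.115 for Hspa8. Dnaja1, Dnajb1 and Hspa8 also lost theirs without cadmium replicate 1 or control replicate 3, and Dnajb1 and Hspa8 without control replicate 2. Among 18 genes of endoplasmic reticulum stress 1 rose and 1 fell, or 1 and 0 with the block (list adjusted p = 0.0580). Trib3, a pseudokinase induced by that stress, rose from 1.89 ± 0.56 to 6.77 ± 1.14 FPKM (log2 fold change 1.43, SE 0.17, adjusted p = 0.00869). Herpud1 fell from 103 ± 11.0 to 61.5 ± 3.26 FPKM (adjusted p = 0.0204, and 0.0672 with the block), a call kept in 1 of the 6 fits that left out a library, that without control replicate 1.

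**Figure D2:**
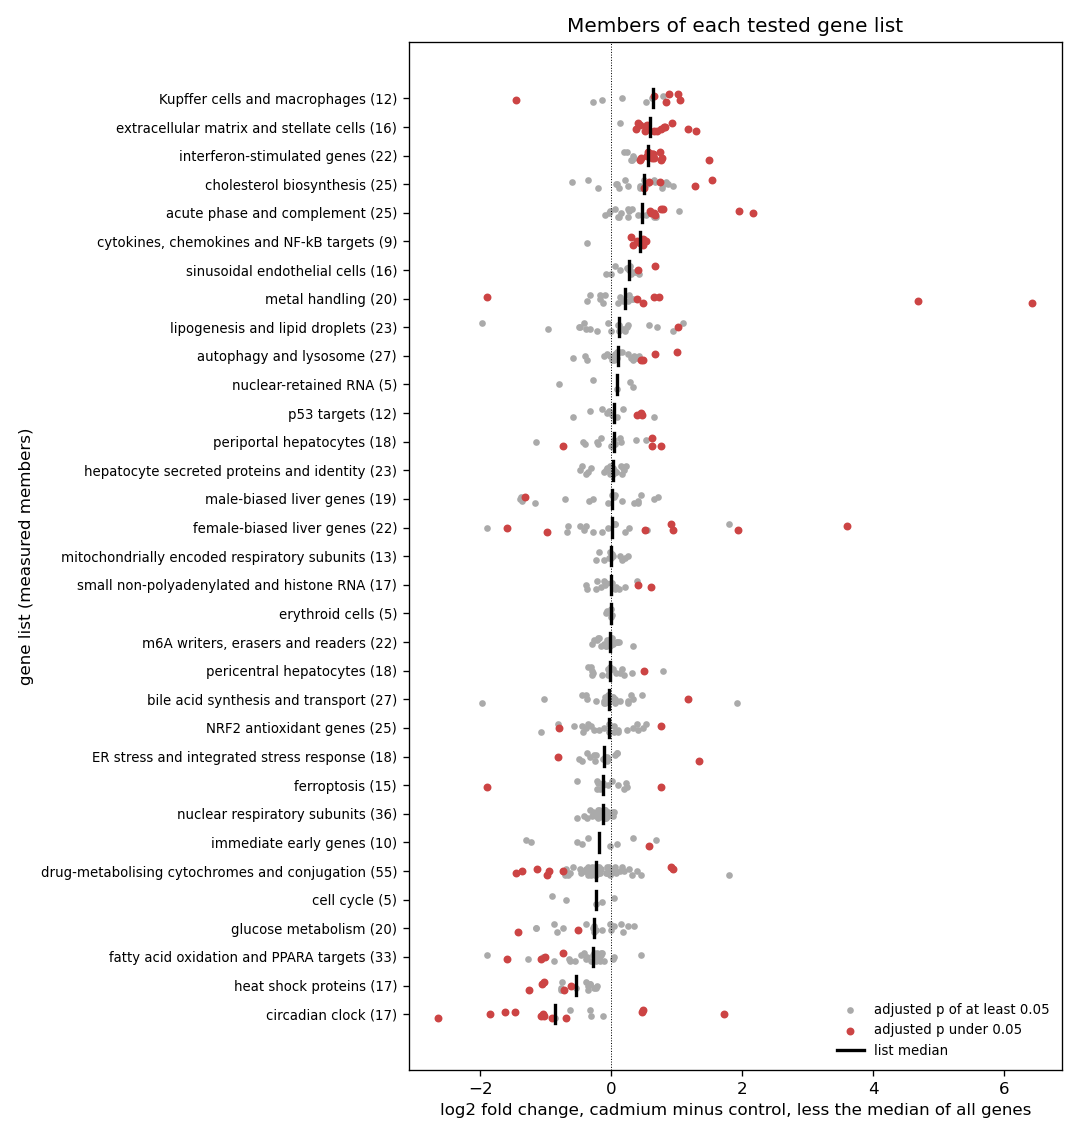
Log2 fold change of each measured member of the 33 tested gene lists, less the median of all genes, with members past an adjusted p of 0.05 in red, others in grey and the list median as a black bar. The clock list has the lowest median, at -0.86, and the Kupffer cell and macrophage list the highest, at 0.64.

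Clock genes fell in part and rose in part. Of 17 measured 3 rose and 9 fell, against 3 and 11 adjusted over the list alone, with a median -0.86 from that of all genes (camera adjusted p = 2.90e-08). The adjusted p was 0.286 with an estimated correlation, and 1 rose and 5 fell with the block. Ciart, a repressor within the clock, fell from 4.38 ± 0.95 to 0.580 ± 0.193 FPKM (log2 fold change -1.76, SE 0.15, adjusted p = 0.00460), Per3 from 4.28 ± 0.44 to 1.74 ± 0.22 FPKM (adjusted p = 0.00688) and Per2 from 6.60 ± 2.07 to 1.55 ± 0.17 FPKM (adjusted p = 0.0118). Nr1d1, which encodes the repressor REV-ERB alpha, rose from 8.84 ± 3.24 to 32.1 ± 2.52 FPKM (log2 fold change 1.81, SE 0.24, adjusted p = 0.0114). Usp2, a rhythmic deubiquitinase, fell from 11.0 ± 2.57 to 1.15 ± 0.98 FPKM (log2 fold change -2.55, SE 0.33, adjusted p = 0.0133), and Noct, a rhythmic phosphatase, from 5.65 ± 2.97 to 0.405 ± 0.210 FPKM (log2 fold change -2.14, SE 0.38, adjusted p = 0.0307). Without cadmium replicate 3 the adjusted p was 0.0564 for Per2, 0.0515 for Nr1d1, 0.0606 for Usp2 and 0.131 for Noct. The call for Noct was also lost without cadmium replicates 1 or 2 or control replicate 3.

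**Figure D3:**
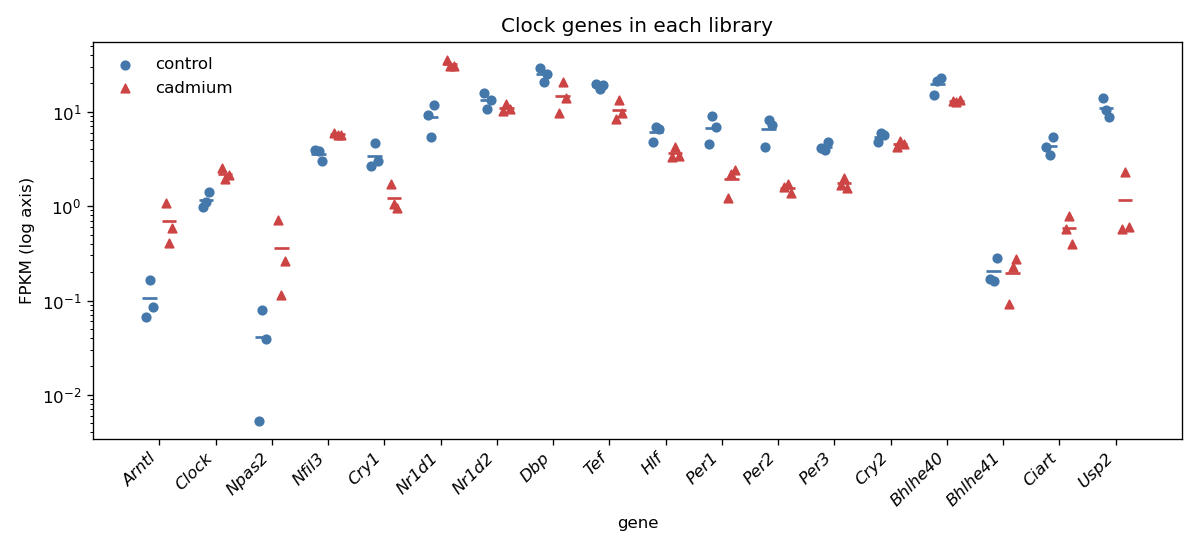
FPKM of 18 clock genes in each library, on a log axis, with control libraries as circles, cadmium libraries as triangles and group means as bars. Ciart, Per2 and Per3 lie lower and Nr1d1 higher in all 3 cadmium libraries than in any control library.

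Interferon-stimulated genes were called higher as a list. Of 22 measured 14 rose and 0 fell, against 21 and 0 adjusted over the list alone, with a median 0.57 from that of all genes (camera adjusted p = 4.81e-10). The adjusted p was 0.398 with an estimated correlation, and 9 rose with the block. Ifi27l2a rose from 1.68 ± 0.41 to 7.07 ± 1.65 FPKM (log2 fold change 1.58, SE 0.18, adjusted p = 0.00869), Oas1a, a sensor of double-stranded RNA, from 0.449 ± 0.10 to 1.66 ± 0.23 FPKM (adjusted p = 0.00739) and Ifit2 from 0.435 ± 0.007 to 1.34 ± 0.23 FPKM (adjusted p = 0.00891). Of 9 measured cytokine, chemokine and NF-kB target genes 7 rose, also when adjusted over the list alone, with a median 0.44 from that of all genes (adjusted p = 0.00217, or 0.398 with an estimated correlation). After quantile normalization 4 rose, and with the block 0. Nfkb2 rose from 1.02 ± 0.185 to 2.01 ± 0.18 FPKM (adjusted p = 0.0144, and 0.0657 with the block), a call lost without cadmium replicate 3 (adjusted p = 0.0738).

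Acute phase and complement genes rose in 8 of 25 cases, or 11 adjusted over the list alone, with a median 0.48 from that of all genes (camera adjusted p = 2.31e-05, or 0.617 with an estimated correlation). With the block 1 rose, and after quantile normalization 3 rose. Saa2, a serum amyloid A protein, rose from 0.726 ± 0.071 to 6.42 ± 2.48 FPKM (log2 fold change 2.04, SE 0.26, adjusted p = 0.0133) and Saa1 from 2.09 ± 0.45 to 15.4 ± 8.93 FPKM (log2 fold change 2.26, SE 0.44, adjusted p = 0.0369, and 0.0579 with the block). These 2 genes are close paralogs that can share reads. Without cadmium replicate 3 their adjusted p were 0.0606 and 0.149, and the call for Saa1 was also lost without any 1 control library, in the deposited log2 values (0.0579) and with voom on recovered reads (0.0892). The fibrinogen chain Fga rose from 466 ± 3.31 to 849 ± 127 FPKM (adjusted p = 0.0278, and 0.0722 with the block), which was lost without 4 of the 6 libraries (control replicates 2 and 3, cadmium replicates 1 and 3), with adjusted p up to 0.125, and after quantile normalization (0.0712).

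Matrix and stellate cell genes rose in 14 of 16 cases, also when adjusted over the list alone, with a median 0.60 from that of all genes (camera adjusted p = 2.00e-09, or 0.398 with an estimated correlation). With the block 7 rose. Col1a1, the main fibrillar collagen chain, rose from 0.863 ± 0.031 to 3.93 ± 0.79 FPKM (log2 fold change 1.39, SE 0.12, adjusted p = 0.00460), Col3a1 from 1.41 ± 0.31 to 4.80 ± 0.69 FPKM (adjusted p = 0.00688), Col1a2 from 0.623 ± 0.154 to 1.80 ± 0.09 FPKM (adjusted p = 0.00809) and Vim from 1.52 ± 0.20 to 3.72 ± 0.33 FPKM (adjusted p = 0.00688).

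Lists of liver cell markers differed in their calls. Of 12 measured Kupffer cell and macrophage markers 5 rose and 1 fell, against 8 and 1 adjusted over the list alone, and the list was not called (adjusted p = 0.0671) but was after each scaling alternative (0.00499 with quantile, 0.00768 with trimmed mean and 0.0200 with upper quartile scaling, 0.00748 in the deposited log2 values), or without control replicate 2 (0.00126) or cadmium replicate 3 (0.0436). In the main fit the list's adjusted p was 0.769 with an estimated correlation. With the block 2 rose and 1 fell. Lyz2, the myeloid lysozyme, rose from 11.3 ± 3.17 to 25.7 ± 2.09 FPKM (adjusted p = 0.0141, and 0.0665 without cadmium replicate 3). Cd163, the scavenger receptor for hemoglobin and haptoglobin, fell from 1.78 ± 0.21 to 0.0768 ± 0.0236 FPKM (log2 fold change -1.37, SE 0.08, adjusted p = 0.00375; chromosome 6, 124304656 to 124330527). Of 16 sinusoidal endothelial markers 2 rose, or 5 adjusted over the list alone, with a median 0.28 from that of all genes (adjusted p = 0.0158, or 0.769 with an estimated correlation). With the block, and after quantile normalization, 0 rose. That list was not called without control replicate 1 or 3 or cadmium replicate 1 or 2, with adjusted p of 0.0783, 0.0581, 0.0936 and 0.0558. Of the 23 hepatocyte identity genes 0 were called, and Alb was at 14969 ± 4095 FPKM in control and 15106 ± 4320 in cadmium (adjusted p = 0.991). Of 18 periportal genes 3 rose and 1 fell and of 18 pericentral genes 1 rose, with list adjusted p of 0.960 and 0.937. With the block 0 periportal genes rose or fell and 1 pericentral gene rose.

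Genes of fatty acid oxidation and PPARA, the receptor that drives them, fell in 4 of 33 cases and rose in 0, as when adjusted over the list alone and as with the block. The median lay -0.28 from that of all genes (camera adjusted p = 5.46e-08, or 0.658 with an estimated correlation). The acyl-CoA thioesterases Acot3 and Acot4 fell from 39.2 ± 8.77 to 13.2 ± 3.05 FPKM (log2 fold change -1.51, SE 0.21, adjusted p = 0.0114) and from 20.3 ± 3.04 to 9.74 ± 1.26 FPKM (adjusted p = 0.0118). Without cadmium replicate 3 their adjusted p were 0.0508 and 0.0606. Acot1 is another of the 4 called genes, with an adjusted p of 0.138 without that library. Acot1, Acot3 and Acot4 lie together on chromosome 12, between 84009490 and 84060402, and AC133183.1 overlaps Acot3 and Acot4. The 4 calls thus come largely from 1 stretch of the genome and alone do not show a broad fall of fatty acid oxidation genes. Whether the lower median of the list reflects such a fall is not settled, since the list was not called with an estimated correlation. Of 20 glucose metabolism genes 2 fell, also adjusted over the list alone, and 0 with the block, with a median -0.26 from that of all genes (adjusted p = 7.23e-04, or 0.398 with an estimated correlation). Tat, a tyrosine aminotransferase, fell from 450 ± 84.3 to 182 ± 57.6 FPKM (adjusted p = 0.0244, and 0.0533 with the block), a call lost without control replicate 2 or 3 or cadmium replicate 1 or 3, with adjusted p up to 0.0973. No nuclear respiratory subunit of 36 was called, while the list was called lower with a median -0.13 from that of all genes (adjusted p = 0.00110, or 0.769 with an estimated correlation).

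Cholesterol synthesis genes rose in 5 of 25 cases, or 11 adjusted over the list alone, with a median 0.50 from that of all genes (camera adjusted p = 0.00206, or 0.769 with an estimated correlation). With the block 0 rose, after quantile normalization 3 rose, and without cadmium replicate 1 the list had an adjusted p of 0.0605. Mvd, a mevalonate pathway enzyme, rose from 5.40 ± 1.04 to 16.1 ± 5.99 FPKM (adjusted p = 0.0248, and 0.0760 with the block), a call lost without any 1 control library or without cadmium replicate 3, with adjusted p up to 0.0846. Of 27 genes of bile acid synthesis and transport 1 rose: Hsd3b7, a bile acid synthesis enzyme, from 46.7 ± 8.14 to 113 ± 13.6 FPKM (log2 fold change 1.26, SE 0.17, adjusted p = 0.00946). Cyp7a1, the rate-limiting enzyme of that synthesis, was at 44.6 ± 26.4 and 10.5 ± 4.87 FPKM (adjusted p = 0.0969) and Cyp8b1 at 20.8 ± 12.0 and 76.4 ± 4.78 FPKM (adjusted p = 0.0503). Autophagy and lysosome genes rose in 4 of 27 cases, or 9 with 1 lower adjusted over the list alone, with a median 0.10 from that of all genes (adjusted p = 0.0255, or 0.711 with an estimated correlation). With the block 1 rose, and after quantile normalization 2 rose and 1 fell. The list's adjusted p was 0.0558 and 0.0511 without cadmium replicates 2 and 3, 0.0501 with a pseudocount of 0.1 and 0.0662 in the deposited log2 values. Atp6v0d2, a proton pump subunit, rose from 2.65 ± 0.345 to 6.81 ± 0.99 FPKM (log2 fold change 1.09, SE 0.12, adjusted p = 0.00809).

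Of 22 measured m6A writers, erasers and readers 0 were called, also adjusted over the list alone, and the list had an adjusted p of 0.466. The demethylases Fto and Alkbh5 were at 2.31 ± 0.05 and 2.74 ± 0.16 FPKM (adjusted p = 0.177) and at 17.6 ± 1.76 and 16.0 ± 1.80 FPKM (adjusted p = 0.554). The writer subunit Wtap was at 9.24 ± 9.03 and 9.73 ± 4.34 FPKM (adjusted p = 0.779). Mettl3 and Mettl14, the catalytic pair of the writer, lay under the filter, at 0.833 to 1.08 and 0.318 to 0.477 FPKM over the 6 libraries, and were not tested.

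Among the other genes with the largest changes, A1bg, a secreted plasma protein, rose from 0.925 ± 0.422 to 25.0 ± 11.2 FPKM (log2 fold change 3.69, SE 0.35, adjusted p = 0.00884; chromosome 15, 60896859 to 60923012). Sult3a1, a sulfotransferase, rose from 7.78 ± 2.38 to 34.7 ± 7.92 FPKM (adjusted p = 0.00843). Both are on the list of female-biased liver genes, of which 5 of 22 rose and 2 fell, also adjusted over the list alone, and which was not called (adjusted p = 0.536). With the block 2 of the 22 rose and 2 fell. Fam129b rose from 0.992 ± 0.058 to 5.68 ± 1.38 FPKM (adjusted p = 0.00460). AC121821.1 (ENSMUSG00000104863), a small RNA gene on chromosome 18, 35557132 to 35557242, rose from 0.0356 ± 0.0341 to 65.4 ± 36.2 FPKM (adjusted p = 0.00869). It overlaps the small nucleolar RNA gene Snora74a on the same strand, so its reads are of uncertain origin. The lincRNA AC127342.1 rose from 0.643 ± 0.371 to 6.05 ± 2.89 FPKM (adjusted p = 0.0220, and 0.0642 with the block), and lost its call without control replicate 2 or 3 or cadmium replicate 3, with adjusted p up to 0.0976, and with voom on recovered reads (0.0554).

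Tsku, a secreted leucine-rich protein, had the largest downward change, from 51.1 ± 24.6 to 1.38 ± 0.895 FPKM (log2 fold change -4.40, SE 0.45, adjusted p = 0.00994; chromosome 7, 98350668 to 98361328). Mfsd2a, a transporter of lysophospholipids, fell from 32.1 ± 6.54 to 8.73 ± 2.64 FPKM (adjusted p = 0.00925), the cell cycle kinase Wee1 from 5.65 ± 1.10 to 0.985 ± 0.186 FPKM (adjusted p = 0.00388) and Coq10b, a coenzyme Q protein, from 6.40 ± 1.31 to 1.40 ± 0.52 FPKM (adjusted p = 0.00869, and 0.0505 with the block). AC133183.1 fell from 20.1 ± 9.82 to 4.98 ± 1.75 FPKM (adjusted p = 0.0370, and 0.0665 with the block). Its span covers Acot3 and Acot4 in part, so reads cannot be assigned to it alone, and its call was lost without any library but control replicate 1, with adjusted p up to 0.123, and after quantile normalization (0.0544).

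The other tested lists were not called. Of 12 p53 targets 3 rose, of 15 ferroptosis genes 1 rose and 1 fell, of 10 immediate early genes 1 rose, of 23 lipogenesis genes 1 rose, of 19 male-biased genes 1 fell and of 17 small and histone RNA genes 2 rose, with list adjusted p of 0.466, 0.272, 0.454, 0.536, 0.144 and 0.805. With the block 0 immediate early, 0 lipogenesis and 0 small and histone RNA genes rose. After quantile normalization 0 small and histone RNA genes rose and 2 ferroptosis genes fell. None was called of 5 cell cycle, 13 mitochondrially encoded respiratory, 5 erythroid and 5 nuclear-retained RNA genes, with list adjusted p of 0.0577, 0.484, 0.604 and 0.960. Too few members were measured to test T and NK cell (0), skeletal muscle (0), neutrophil (1), pancreatic acinar (1), adipocyte (2), B and plasma cell (3) and cholangiocyte (3) markers. Of these markers 1 neutrophil and 1 cholangiocyte marker were called higher, and 0 of either with the block. After quantile normalization the neutrophil marker was not called. Leaving out 1 library brought 5 uncalled lists past the threshold, the Kupffer cell and macrophage list upward, as given above, and 4 downward: NRF2 genes without control replicate 1 or cadmium replicate 3 (adjusted p = 0.0366 and 0.0439), endoplasmic reticulum stress without control replicate 3 or cadmium replicate 3 (0.0361 and 0.0237), cell cycle without control replicates 2 or 3 or cadmium replicate 3 (0.0203, 0.0232 and 0.0348) and male-biased genes without control replicate 2 or cadmium replicate 2 (0.0187 and 0.0163). Of the 33 lists 13 were called with the preset correlation and 0 with an estimated one. Fry, which asks whether a list's genes move one way on balance without comparing them with other genes, called 6.

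The authors' deposited table, which covers 34352 genes, has 1277 genes higher and 1082 lower in cadmium at an FDR under 0.05. Among the 9908 genes tested here 1612 passed that FDR in the authors' deposited table, 686 higher and 926 lower. Of the 959 genes called from FPKM 793 were among them, all in the same direction: 614 of 779 higher and 179 of 180 lower. Independent lists of these sizes would share 53.9 and 16.8. Both sets of calls come from the same 6 libraries, so their overlap is not a replication.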

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

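The alternatives that used the deposited log2 values, voom, upper quartile or trimmed mean scaling for lists, and the block together with quantile normalization were chosen after the data were seen. The number of called genes was 959. It was 248 with the replicate block, 37 with no filter on low FPKM (34351 genes tested), 279 with a minimum FPKM of 5 (3922 genes tested), 1961 with library weights, 107 with an absolute log2 fold change of at least 1, and 80 with the replicate block and quantile normalization together. The cause was not tested, except that the fold minimum only removes calls. Leaving out 1 library gave 101 to 781 called genes, the lowest without cadmium replicate 3 and the highest without control replicate 1, with 1 sample fewer in each fit. Under a pseudocount of 0.1, the other scalings, a plain variance model, the deposited log2 values (874) and voom on recovered reads (869) the total stayed within 1.5 times. The set of genes was less stable than the total. Of the 959 genes, 525 were also called in the same direction after quantile normalization, 543 after trimmed mean and 687 after upper quartile scaling. The number was 559 in the deposited log2 values, 558 with voom, 764 with the plain variance model and 890 with the pseudocount of 0.1. Camera with an estimated correlation called 0 lists in place of 13. Leaving out 1 library gave 11 to 16 called lists, and the replicate block 13. The block changed no list call. Among the 162 genes set by the naming rule it ended 44 calls and added 2, and the report gives this beside those of them that it prints. The authors' deposited table holds 5219 genes at an unadjusted p under 0.05, in place of 2359 at its FDR. Of the 162 genes of that rule 87 were called. Of these, 43 were called with the block, 71 after quantile normalization and 24 in every fit that left out a library. In the 13 alternatives run for them, 0 of the 87 changed sign. Depth was at least 42115960 reads per library, and the number of libraries limits the precision: 3 against 3 cannot reach an exact p under 0.1 for 1 gene alone.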

Other observations

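The genes and tests in this part were chosen after the values were seen. Genes of MHC class II, which present antigen on immune cells, were called higher in 5 of 5 measured cases, with the block and after quantile normalization as well, and in 3 without cadmium replicate 3. H2-Eb1 rose from 4.20 ± 0.72 to 12.9 ± 1.01 FPKM (SD, n = 3; adjusted p = 0.00460), H2-Aa from 2.09 ± 0.63 to 6.21 ± 0.38 FPKM (adjusted p = 0.00869) and Cd74, the invariant chain, from 12.8 ± 4.11 to 36.4 ± 3.10 FPKM (adjusted p = 0.0114, and 0.0528 without cadmium replicate 3). H2-DMb1 lost its call there too (0.0564). Of 11 measured collagen genes 10 were called higher, 8 after quantile normalization, 6 with the block and 5 without cadmium replicate 3. These are 2 of 8 gene families looked at in this way. Among the others, 6 of 7 guanylate-binding protein genes were called higher (3 with the block, and 1 without cadmium replicate 3). Of 61 cytochrome P450 genes 5 were called higher and 2 lower (0 and 1 with the block), of 55 Hsp and Dnaj genes 1 and 7 (0 and 3) and of 14 glucocorticoid-inducible genes 2 and 4 (2 and 2). Leaving out 1 library gave 0 to 5 higher and 0 to 6 lower for the P450 genes. The ranges were 0 and 0 to 6 for Hsp and Dnaj genes, and 1 to 2 and 0 to 7 for glucocorticoid-inducible genes. After quantile normalization 3 P450 genes and 0 Hsp and Dnaj genes were higher. Of 12 sulfotransferases 2 were called higher and 0 lower (2 and 0), and of 10 COQ genes 1 and 1 (1 and 0). Leaving out 1 library gave 2 higher and 0 to 3 lower sulfotransferases. Macrophage genes under the filter, which were not tested, went both ways: Cx3cr1 had 16 to 28 reads in the control and 147 to 270 in the cadmium libraries, Gpnmb 0 to 8 and 49 to 91, and Timd4, a resident Kupffer cell receptor, 46 to 97 and 13 to 17. Clec4f, another Kupffer cell marker, was at 8.99 to 11.2 FPKM in control and 10.4 to 14.3 FPKM in cadmium.

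Some genes were near all or none. Gm12963, annotated as an antisense RNA on chromosome 4, had 820 to 1937 reads in the control libraries and was listed at 0 in all 3 cadmium libraries. AC157822.1, a small RNA gene within Rn7s2, had 10 reads in control replicate 1 and 40452 to 99031 in the other libraries. In control replicate 1 Sult2a1 stood at 5.61 FPKM, against 122 to 172 FPKM in the other controls and 43.3 to 47.5 FPKM in cadmium. It was not called (adjusted p = 0.949), but was called without control replicate 1 (adjusted p = 0.0122).

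All 6 libraries labelled male carried Xist. Its lowest level was 19.7 FPKM, and 21647 to 41199 reads were recovered per library. Ddx3y, Uty, Kdm5d and Eif2s3y, single-copy genes of the Y chromosome, had at most 1 read in all per library. Missing annotation was argued against by the 175 Y-linked protein-coding genes listed in the FPKM table, and an effect of cadmium by the control libraries, which carried Xist at 19.7 to 25.8 FPKM. The male-specific Hsd3b5 stayed at 0.547 FPKM or lower and the female-specific Cyp2b9 at 106 FPKM or higher, but the male-biased Cyp2d9 was at 11.3 to 30.3 FPKM and the female-biased Cyp3a41a at 3.32 FPKM in control replicate 1, against 17.6 to 74.2 in the others. Cyp4a12a, also on the male-biased list, had 0 reads in every library but cadmium replicate 2, which had 5. The levels of Xist and of the Y-linked genes argue against male livers for all 6 libraries. Livers from female mice remain a candidate explanation. How the labels came to give male mice cannot be settled from the sources used here.

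Clock genes differed between the groups in both directions. A general drop of clock gene expression was argued against, since 3 clock genes were called higher in cadmium. Of these, Nr1d1 (log2 fold change 1.81, SE 0.24) kept its call with the block and Clock and Nfil3 did not (adjusted p = 0.0705 and 0.0584). Without cadmium replicate 3 all 3 calls were lost. Clock genes under the filter were not tested. Among them Arntl was at 0.0667 to 0.164 FPKM in control and 0.404 to 1.09 FPKM in cadmium. Npas2 was at 0.00535 to 0.0785 and 0.115 to 0.705 FPKM. Bhlhe41 overlapped, at 0.161 to 0.281 and 0.0912 to 0.277 FPKM. A different clock phase in the 2 groups was tested by giving 18 clock genes their usual time of peak in mouse liver, late night to dawn or day to dusk. The first such table left out Nr1d1, Nr1d2, Cry1, Cry2 and Bhlhe40 and compared medians, which favoured a phase difference, and it was replaced by one that holds them. Of 11 called genes 9 moved with their assigned time and 2 against it (Cry1 and Nr1d1). Apart from Clock and Nfil3, those that moved with it were day-to-dusk genes that fell. A fall of those genes without a difference in phase would give the same. With the block the counts were 5 and 1 (Nr1d1) of 6, and all 5 were genes that fell. Without 1 library the counts were 2 to 9 and 0 to 2. Each assigned time spans many hours, so genes with the same assigned time can move in opposite directions under a smaller shift. A phase difference was predicted to leave no called gene against its assigned time, and this was not met. Because of the wide spans, the 2 genes do not argue against a phase difference either, so the test cannot decide. A phase difference may account for part of the pattern and stays open. Different hours of liver collection cannot be told apart from an effect of cadmium on the clock, because 0 of the 6 samples' labels give an hour. The same limit holds for every other called gene, in any list, whose level varies over the day. Which of the called genes do so was not tested.

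More genes were called higher than lower in cadmium, 779 against 180. Low-expressed genes were argued against as the reason, since 73.5% of calls were higher with a minimum FPKM of 5. After quantile normalization 53.8% of calls were higher, consistent with a scaling of the FPKM to each library's total as the source of the skew. In the deposited log2 values 381 genes were called higher and 493 lower, and with voom on recovered reads 380 and 489. The excess thus reversed under scaling by size factors, and a true excess of higher genes in cadmium was not shown. It stays open only because quantile normalization, and possibly size factors, would remove a true excess too.

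The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 959 genes and the highest of the others 2. Every other split mixes the groups, so the difference between cadmium and control adds to its residual spread and lowers its calls. The counts of the other splits are therefore no measure of what chance alone would give. Of the 10 splits 1, the real one, called as many. Among the 4 splits that part all 3 numbered pairs, the others called 1, 1 and 2 genes.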
